A study of Homo sapiens with 6 samples.

How the data were processed

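RNA was measured in 6 libraries of the H1 human embryonic stem cell line, at passages 40 to 60 per the labels. The cells carried a doxycycline-inducible short hairpin RNA against EXOSC3, which encodes a subunit of the RNA exosome, the complex that degrades and trims RNA from its 3' end. They also carried either an empty vector (named PB in the labels) or a transgene, EXOSC3r, made resistant to the hairpin. There was 1 PB library without and 1 with doxycycline (dox), and the same pair was made for each of 2 EXOSC3r clones. Per the labels' protocols, ribosomal RNA was removed and stranded total RNA libraries were prepared.

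Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.36 and Salmon 0.13.0 were used. The index source, options and genome build were not given in the sources used here. Each of the deposited tables holds, per the file headers, an estimated count, a TPM value, a length and an effective length for 1047 sequences. Of these, 1045 bear names of repeat consensus sequences, and the others are RefSeq transcripts of ACTB and GAPDH, matched by accession to a RefSeq table of GRCh38.p14. The deposited estimated counts are not normalised. The deposited TPM values are scaled to the same total in each library over these sequences alone, so that Alu takes most of each total. A consensus stands for many genomic copies and has no single position, and reads that fit several related sequences were divided between them by estimation. The division between near-identical members is uncertain, so families were also summed. Reads of a repeat lying inside a gene's transcript also count for the repeat. EXOSC3 itself was not analysed here, so the depletion and its rescue were not checked.

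The total of assigned estimated counts was between 3745260 and 5260200 per library. These totals cover only reads given to the 1047 sequences and are not sequencing depth. Counts were rounded to whole numbers. A sequence was tested if it had at least 10 counts in at least 1 library, which left 699 of 799 with any count. Differences were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM scaling, 4 group means and Benjamini-Hochberg adjustment at 0.05. This fit has 2 residual degrees of freedom, both from the clones, and each lone PB library is assumed to vary like a clone. The biological coefficient of variation was 12.2%. The standard error of a log2 fold change was the change divided by the square root of the F statistic. Values per library are TMM-scaled CPM, counts scaled to a common library size. P-values measure the spread between clones. Pairs of libraries differed with a chi-square per degree of freedom from 22.2 to 902, so none was a copy of another.

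Repeat lists were defined by name patterns before the data were examined. Of these, 14 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated one. They were also tested with fry, another list test of limma. The pattern for DNA transposons also took 54 tested names of MER elements that are of the LTR type, and the list was tested again without them. The text may name, per comparison, up to 10 sequences in each direction, first those that passed by size of change and then those with the smallest p. It may also name the members of the young L1, HERVH/LTR7, HERVK/LTR5 and SVA lists. Only some of these sequences are named. This rule for what may be named was set before the data were examined, and names outside it are marked as chosen later.

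The dox and no-dox library of a clone come from the same cell line, so clone numbers pair the samples. The deviations of clone 1 from the mean of both clones, without and with dox, had a Pearson correlation across sequences of 0.15 over 699 sequences and 0.60 over the 253 with a mean of at least 100 CPM; sequences are not independent replicates. A fit with the line as a block has 1 residual degree of freedom. It suits the dox responses, which lie within lines; for EXOSC3r against PB cells, which are different lines, it takes the spread between clones out of the error. Its values stand beside the results they change.

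Alternatives planned before the data were examined were DESeq2 size factors, total counts, DESeq2 1.42.0, no count filter, a filter of at least 10 counts in all 6 libraries, limma on log2(TPM + 1) and on log2(TPM + 0.1), an offset for effective length, the block, leaving out each clone library, and pooled controls. Scaling to ACTB and GAPDH, leaving out Alu, ACTB and GAPDH, and summing near-identical families were chosen after seeing the data.

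The code was tested on simulated counts for the 699 sequences with 200 changed. For dox in PB cells, 13.4% of sequences changed by 0.5 on the log2 scale were recovered, 58.2% of those changed by 1 and 78.8% of those changed by 2, and 3 of 103 calls were false. For dox in EXOSC3r cells the shares were 28.4%, 73.1% and 89.4%, and 5 of 133 calls were false. The test therefore misses many changes smaller than 1 on the log2 scale. All libraries were simulated with the fitted spread, so the lone PB libraries varied like clones by construction. The share of false calls hence does not test that assumption. With 200 sequences changed, far more than were called in the data, the adjustment is milder and recovery may be too high.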

Results

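Repeat-derived RNA was measured in H1 human embryonic stem cells in which a dox-inducible hairpin targets EXOSC3, with an empty vector (PB) or a hairpin-resistant EXOSC3 transgene (EXOSC3r). The total of assigned estimated counts was 4493010 in PB cells and 4565800 in PB cells with dox. In EXOSC3r clone 1 it was 4620770 without and 5260200 with dox, and in clone 2 it was 3941990 and 3745260. The PB condition had 1 library per arm and hence no replicate of its own, and the EXOSC3r condition had 2 clones per arm. The design compares the response to hairpin induction without and with the transgene.

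Alu, the most abundant short interspersed repeat, took 37.3% of assigned counts in PB cells (95% Clopper-Pearson interval 37.25 to 37.34) and 32.99% in PB cells with dox (32.94 to 33.03). It took 45.4% (45.37 to 45.47) and 52.5% (52.48 to 52.56) in clone 1 without and with dox, and 41.8% (41.78 to 41.88) and 40.1% (40.09 to 40.18) in clone 2. The intervals cover counting error only. ACTB (GRCh38.p14, chromosome 7, 5527148 to 5530601) took between 4.82% and 6.55% and GAPDH (chromosome 12, 6534517 to 6538371) between 7.54% and 10.4%. With dox the Alu share was lower in PB cells and clone 2 and higher in clone 1. Alu, ACTB and GAPDH were singled out after their values were seen.

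**Figure D1:**
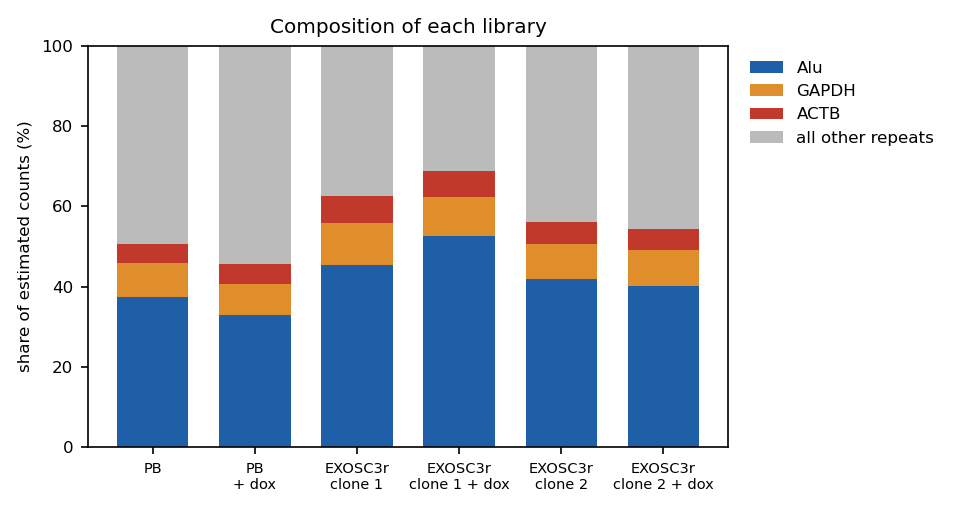
Share of estimated counts (vertical axis, percent) taken by Alu, GAPDH, ACTB and all other repeats in each of the 6 libraries (1 bar each). Alu ranges from 32.99% in PB cells with dox to 52.5% in clone 1 with dox.

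In PB cells, dox raised 6 of 699 sequences and lowered 0 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Alpha satellite sequences, the tandem repeats of centromeres, were among them: ALRb went from 34.1 to 113 CPM (log2 change 1.72 ± 0.20, SE, adjusted p = 0.018), ALR1 from 126 to 327 CPM (1.37 ± 0.16, adjusted p = 0.018) and ALR from 186 to 408 CPM (1.14 ± 0.15, adjusted p = 0.027). ACRO1, a satellite of acrocentric chromosomes, went from 2.73 to 29.3 CPM, a 10.6-fold change (log2 3.41 ± 0.47, adjusted p = 0.034) that rested on 13.7 and 162 estimated counts. MER22 rose 2.13-fold, from 202 to 431 CPM (log2 1.09 ± 0.11, adjusted p = 0.015), and 6kbHsap rose 1.87-fold, from 1529 to 2863 CPM (log2 0.91 ± 0.09, adjusted p = 0.015). At an unadjusted p under 0.05 there were 28 sequences, fewer than that threshold would give among 699 tests without any change.

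Of the 20 tested satellites, 4 rose in PB cells with dox and 0 fell, and 5 rose when adjusted over the list alone. MER22 and 6kbHsap matched no name pattern, so none of the list tests covers them. The lists go by name alone, which leaves open whether these sequences are satellites. The list as a whole did not pass (median log2 change 0.05, adjusted p = 0.29, and 0.98 with an estimated correlation), though it did with limma on log2(TPM + 1) (adjusted p = 0.017, and 0.996 with an estimated correlation). ALR2, another alpha satellite, had a log2 change of 0.81 ± 0.20 (adjusted p = 0.46). Of the 5 sequences of HERVH, an endogenous retrovirus transcribed in human pluripotent cells, and its LTR7 promoters, none passed: HERVH went from 28393 to 35679 CPM (log2 0.33 ± 0.12, adjusted p = 1.00), and LTR7B had a log2 change of -0.40 ± 0.21. None of the 11 young L1 sequences passed. L1HS, the youngest human L1 group, went from 54063 to 65035 CPM (log2 0.27 ± 0.13, adjusted p = 1.00). HERVK had a log2 change of -0.60 ± 0.41, LTR5_Hs of -0.19 ± 0.32 and SVA_A of 0.09 ± 0.11, and none of the 3 passed.

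The PB calls rest on a spread estimated from the clones: without the clone 1 library lacking dox, 0 sequences passed. Limma on TPM kept 1 of the 6 (ACRO1) and DESeq2 size factors 4, total counts called 2, of which 1 was among the 6, scaling to ACTB and GAPDH called 1, which was not, and summing near-identical families called 2, MER22 and 6kbHsap, with the ALR family at 0.86 ± 0.18 (adjusted p = 0.40).

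**Figure D2:**
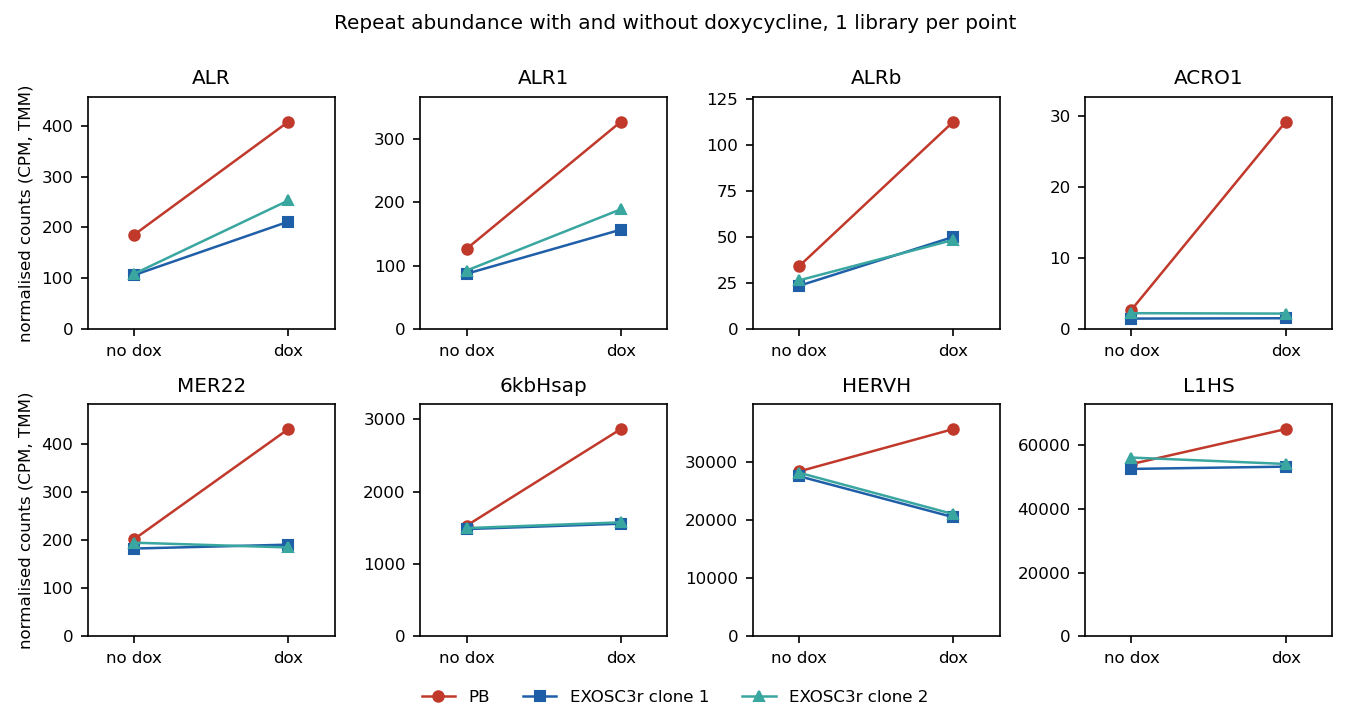
TMM-scaled counts (CPM, vertical axis) of 8 sequences without and with dox, 1 library per point, with lines joining the libraries of PB cells and of each EXOSC3r clone. MER22 is at 431 CPM in PB cells with dox and between 183 and 202 CPM in the other libraries, whereas ALR is higher with dox in each of the 3 lines.

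In EXOSC3r cells, dox raised 1 of 699 sequences, ALR, and lowered 0. ALR went from 108 ± 1.75 to 232 ± 29.5 CPM (SD, n = 2 clones), a log2 change of 1.11 ± 0.11 (SE, edgeR, adjusted p = 0.026). It was higher with dox in 2 of 2 clones, from 106 to 211 CPM in clone 1 and from 109 to 253 CPM in clone 2. ALR1 (log2 0.95 ± 0.12, adjusted p = 0.052) and ALRb (0.98 ± 0.15, adjusted p = 0.11) did not pass. MER22 was at 189 ± 8.62 CPM without and 188 ± 4.13 CPM with dox, 6kbHsap at 1489 ± 9.49 and 1566 ± 13.2 CPM, and ACRO1 at 1.87 ± 0.54 and 1.86 ± 0.47 CPM. At an unadjusted p under 0.05 there were 22 sequences, again fewer than that threshold would give without any change.

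The 5 HERVH and LTR7 sequences were lower with dox as a list (median log2 change -0.39, camera adjusted p = 0.0016). They did not pass with an estimated correlation (adjusted p = 0.90) or with fry (adjusted p = 0.61). Over the alternatives this median lay between -0.47 and -0.24. HERVH went from 27872 ± 422 to 20784 ± 373 CPM (SD, n = 2), a log2 change of -0.42 ± 0.09 (edgeR, adjusted p = 0.39 over all sequences). Adjusted over the list alone, 2 of the 5 passed, HERVH and LTR7Y (log2 -0.39 ± 0.09). The satellites were higher as a list (median 0.27, camera adjusted p = 0.022), again not with an estimated correlation (adjusted p = 0.90) or with fry (adjusted p = 0.61). Of these, 3 of 20 passed when adjusted over the list alone. Of the 11 young L1 sequences none passed, and L1HS had a log2 change of -0.02 ± 0.10.

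With the clone as a block, 9 sequences passed in EXOSC3r cells, 4 higher (ALR, ALR1, HUERS-P1 and HSMAR1) and 5 lower (HERVH, LTR7A, LTR7B, LTR7Y and GOLEM); HERVH then had an adjusted p of 0.015. ALR did not pass without the clone 1 library lacking dox or without the clone 2 library with dox (0 calls each), and the 2 list calls were also lost without either, with total counts and with limma on log2(TPM + 0.1); DESeq2 size factors, total counts and scaling to ACTB and GAPDH also called 0, DESeq2 called 4 and summed families 0.

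The response to dox was then compared directly between PB and EXOSC3r cells. No sequence passed in the edgeR interaction test, with 9 at an unadjusted p under 0.05, fewer than that threshold would give without any change. The smallest adjusted p values were those of MER22, whose response was larger in PB cells by 1.10 ± 0.13 on the log2 scale (adjusted p = 0.076), and 6kbHsap, larger by 0.83 ± 0.11 (adjusted p = 0.076). HERVH differed by 0.75 ± 0.15 and ACRO1 by 3.41 ± 0.69 (both adjusted p = 0.40). Adjusted over the list alone, 1 of 5 HERVH/LTR7 sequences (HERVH) and 1 of 20 satellites (ACRO1) passed. For ALR the difference was 0.03 ± 0.18, for ALR1 0.42 ± 0.19 and for ALRb 0.74 ± 0.24 (adjusted p = 1.00), and none of the 3 passed. With the line as a block 3 sequences passed, namely MER22, 6kbHsap (adjusted p = 0.024 and 0.020) and HERVH (adjusted p = 0.020); DESeq2 also called 3, and limma on log2(TPM + 0.1) called 7.

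**Figure D3:**
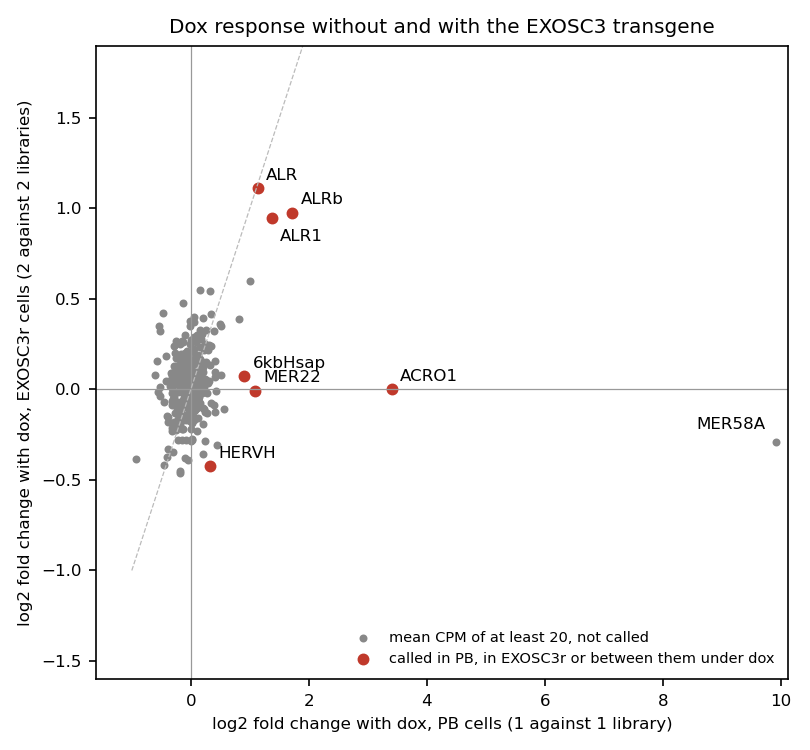
Log2 fold change with dox in PB cells (horizontal axis, 1 against 1 library) against that in EXOSC3r cells (vertical axis, 2 against 2 libraries) for 455 sequences, namely those with a mean of at least 20 CPM or a call; the dashed line marks equal changes. The 7 sequences called in PB cells, in EXOSC3r cells or between them under dox are in red, with ALR at 1.14 and 1.11 and MER22 at 1.09 and -0.01. The grey point at the far right, MER58A, was estimated near 0 in the PB library without dox and did not pass with TMM scaling of all 6 libraries in edgeR, though it did with total counts, with ACTB and GAPDH scaling, without either clone library with dox and with limma on TPM.

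Between EXOSC3r and PB cells under dox, 7 sequences were lower in EXOSC3r cells and 0 were higher (edgeR). At an unadjusted p under 0.05 there were 53, more than that threshold would give without any change. The 7 were the 6 that rose in PB cells and HERVH. Both comparisons use the same PB library with dox, so the overlap is not independent support. For ALR a log2 difference of similar size, -0.79 ± 0.13, was present without dox, though it did not pass over all sequences. ALR1 (-0.49 ± 0.14) and ALRb (-0.45 ± 0.18) were also lower without dox, by less than under dox, and did not pass either. ACRO1 was lower by a log2 change of -3.95 ± 0.40 (adjusted p = 0.011), MER22 by -1.198 ± 0.09 (adjusted p = 0.0055), ALRb by -1.19 ± 0.16 (adjusted p = 0.035), ALR1 by -0.92 ± 0.13 (adjusted p = 0.040), 6kbHsap by -0.87 ± 0.07 (adjusted p = 0.0064) and ALR by -0.81 ± 0.12 (adjusted p = 0.046). HERVH stood at 20784 ± 373 CPM (SD, n = 2) against 35679 CPM in PB cells, a log2 difference of -0.78 ± 0.10 (adjusted p = 0.035). Of the satellites 4 of 20 were lower, 5 when adjusted over the list alone, while the list median was -0.09 (adjusted p = 0.083). CER, another satellite, had a log2 difference of 1.18 ± 0.26 (adjusted p = 0.34) and passed when adjusted over the list alone. L1HS had -0.28 ± 0.12 and did not pass (adjusted p = 0.61).

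HERVH did not pass without the clone 1 library lacking dox (3 calls), the clone 1 library with dox (3) or the clone 2 library lacking dox (6), ALR and ALR1 did not without the first 2, ALRb did not without the first 2 or the clone 2 library with dox (11 calls), and the summed HERVH and LTR7 family had -0.54 ± 0.13 (adjusted p = 0.62). ALR and ALR1 were also lost with DESeq2 size factors, HERVH, ALR, ALR1 and 6kbHsap with total counts, all but ACRO1 with limma on TPM and with ACTB and GAPDH scaling, and ALR without a count filter (adjusted p = 0.052). With the line as a block 22 sequences passed (10 higher and 12 lower, including all 7 and, at an adjusted p of 0.046, CER and L1HS), but the comparison is between lines and the block takes the spread between clones out of its error, so these calls are set against the spread within lines alone.

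Without dox, 0 sequences differed between EXOSC3r and PB cells in the edgeR test. The 16 at an unadjusted p under 0.05 were fewer than that threshold would give without any change. DESeq2 also called 0, whereas total counts called 1 and limma on TPM 2. ALR was at 108 ± 1.75 CPM (SD, n = 2) in EXOSC3r and 186 CPM in PB cells (log2 difference -0.79 ± 0.13, adjusted p = 0.49), and it passed when adjusted over the 20 satellites, the list alone. HERVH (-0.03 ± 0.10), MER22 (-0.10 ± 0.09) and 6kbHsap (-0.04 ± 0.08) did not pass either. The satellite median was -0.14 (camera adjusted p = 0.075) and that of 27 older primate L1 sequences was -0.07 (adjusted p = 0.099), and neither list passed with an estimated correlation (adjusted p = 0.87 for both). With the line as a block both had an adjusted p of 0.047, but the block leaves the spread between clones out of the error of this comparison between lines, so the value is no support for a difference.

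The remaining lists covered older and mammalian-wide L1, other endogenous retroviruses and their LTRs, MaLR elements, old non-LTR elements and DNA transposons. None passed in PB cells, where the medians of the 14 tested lists lay between -0.09 and 0.05. In EXOSC3r cells none but the HERVH/LTR7 and satellite lists passed, and neither did with an estimated correlation (camera adjusted p = 0.90). The other 12 medians there lay between -0.02 and 0.17. Under dox the 14 medians of EXOSC3r minus PB lay between -0.09 and 0.28, and none passed, whereas the satellite list passed with total counts (adjusted p = 0.0020) and with limma on TPM, and the DNA transposon list without LTR-type MER names (adjusted p = 0.041). With an estimated correlation none of these passed (adjusted p between 0.989 and 0.997).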

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

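All tests of explanations in this part were chosen after the results were seen. The dox responses of ACRO1 and HERVH differed between PB and EXOSC3r cells in the interaction test when adjusted over their lists alone, by 3.41 ± 0.69 (adjusted p = 0.046, 20 satellites) and by 0.75 ± 0.15 on the log2 scale (adjusted p = 0.0097, 5 sequences). Over all 699 sequences neither passed (adjusted p = 0.40). ACRO1 and HERVH were found by searching each of the 14 tested lists, and the values for a list alone are not adjusted for the number of lists.

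MER22, 6kbHsap and ACRO1 were higher with dox in PB cells, whereas in EXOSC3r cells their log2 changes were -0.01 ± 0.08, 0.07 ± 0.06 and 0.0013 ± 0.48. Over 6 scalings the lowest of their changes was 0.89 on the log2 scale (6kbHsap, DESeq2 size factors, SE 0.08). A scaling moves all sequences of a library nearly alike. Against TMM, the other scalings moved the sequences in PB cells by a median of -0.0172 to 0.216. Such shifts could not remove the changes, so this range does not test library scaling as a cause. It shows only that the 3 rose relative to the median sequence with each scaling. With total counts the MER22 change was 1.18 ± 0.51 against 1.09 ± 0.11, and its call ended because the SE grew. Carry-over of genomic DNA, which would raise abundant genomic repeats such as L1M, stays open because the L1M change depends on the scaling: its share of counts rose by 0.155 percentage points (6kbHsap by 0.173) while that of Alu was lower. With TMM, which centres on such repeats, L1M went from 22710 to 22633 CPM, and relative to the summed ACTB and GAPDH counts from 19.3% to 21.7% (6kbHsap from 1.302% to 2.75%). Loss of EXOSC3 that the transgene makes good may account for the pattern, but a difference of this 1 library other than EXOSC3 loss cannot be told apart from it, since there was 1 PB library with dox.

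ALR, ALR1 and ALRb were higher with dox in PB cells and in both clones, ALRb with log2 changes of 1.72 ± 0.20 in PB and 0.98 ± 0.15 in EXOSC3r cells, a difference of 0.74 ± 0.24 that did not pass. Reads moved between alpha satellite sequences as the whole cause are argued against by the summed ALR family, whose lower change of the 2 conditions was 0.71 ± 0.13 on the log2 scale, although the sum did not pass (adjusted p = 0.86). EXOSC3 loss fully reversed by the transgene is argued against as the sole cause by the lowest change of the 3 in EXOSC3r cells, 0.95 ± 0.12. Doxycycline or shRNA expression itself, or a transgene that restores EXOSC3 in part, may account for the rise, and these cannot be told apart because there were 0 libraries without the EXOSC3 shRNA.

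HERVH was higher with dox in PB cells (log2 0.33 ± 0.12) and lower in EXOSC3r cells (-0.42 ± 0.09), neither passing over all sequences. Over 6 scalings the lowest difference of responses was 0.74 on the log2 scale (SE 0.14). Against TMM, the other scalings moved this difference for all sequences by a median of -0.0081 to 0.341. Such shifts could not remove it, so this range does not test library scaling as a cause. With total counts the difference was 0.88 ± 0.61, or 0.75 relative to the shift of all sequences by 0.13. Reads moved between HERVH and LTR7 sequences are argued against for the fall in EXOSC3r cells, where their sum changed by -0.42 ± 0.11. In PB cells the sum changed by 0.16 ± 0.16, so moved reads stay open for the rise there. The responses of the sum differed by 0.59 ± 0.19, although this did not pass (adjusted p = 1.00). The transgene may set the difference, but a line difference other than the transgene cannot be told apart from it with 1 empty-vector line.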

How the results depend on the processing

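Scaling to ACTB and GAPDH, leaving out Alu, ACTB and GAPDH, summing families and taking LTR-type MER names out of the DNA transposon list were chosen after seeing the data; the causes of the changes below were not tested. Total counts, ACTB and GAPDH scaling and TPM moved the median of all sequences by over 0.1 on the log2 scale, by up to -0.78 (TPM, EXOSC3r minus PB under dox), and the log2 values in this part are relative to such shifts. Smaller shifts are left in, namely 0.0886 for total counts in PB cells and -0.0408 in EXOSC3r cells. Of 1285 alternative values of 80 named changes, 1144 kept direction and side of the threshold, 76 were weaker, 37 stronger and 28 reversed. Most of the 80 had not passed with the main settings, and only a change that had passed can become weaker. The 76 therefore all concern the calls. Each call passed in between 7 of 15 alternatives (ALR, EXOSC3r minus PB under dox) and 15 of 15 (ACRO1, same comparison). The spread rests on 2 clones, so the count of calls moved with the settings. Over the alternatives the MER22 change in PB cells lay between 1.08 and 1.18 (total counts, its shift included), but its adjusted p between 6.6e-05 and 1.00. Most alternatives take the PB change from the same pair of libraries. The narrow range therefore does not show how firm that change is.

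For dox in PB cells (6 calls), DESeq2 size factors gave 4, without ACRO1 and ALR, the filter on all 6 libraries 5, not testing ACRO1, total counts 2, limma on TPM 4 (pseudocount 1) and 5 (pseudocount 0.1), each sharing only ACRO1 with the 6, ACTB and GAPDH scaling 1, summed families 2, the other 5 libraries as control 3, and leaving out a clone library 0 to 7. For dox in EXOSC3r cells (1 call), DESeq2 size factors gave 0, total counts 0, DESeq2 4, the filter on all 6 libraries 2, limma on TPM 2 and 4, neither with ALR, effective length 2, ACTB and GAPDH scaling 0, leaving out Alu, ACTB and GAPDH 3, summed families 0, and leaving out a clone library 0 to 2. For the difference of responses (0 calls), total counts gave 1, DESeq2 3, the filter on all 6 libraries 2, limma on TPM 3 and 7, ACTB and GAPDH scaling 1, leaving out Alu, ACTB and GAPDH 3, and leaving out a clone library 0 to 1. Under dox (7 calls), DESeq2 size factors gave 5, without ALR and ALR1, no count filter 6, without ALR, the filter on all 6 libraries 6, not testing ACRO1, total counts 3, limma on TPM 4 and 7, each sharing only ACRO1 with the 7, ACTB and GAPDH scaling 1, summed families 3, and leaving out a clone library 3 to 11, HERVH being lost in 3 of the 4 cases. Without dox (0 calls), total counts gave 1, limma on TPM 2 and 2, ACTB and GAPDH scaling 1, and leaving out a clone library 0 to 1. The list tests (2 calls) gave 1 with total counts and 1 with limma on log2(TPM + 0.1), in each case not one of the 2 but the satellites under dox (adjusted p = 0.0020 and 0.00012), which also passed with log2(TPM + 1) (4.5e-06), 0 with an estimated correlation and 0 to 2 leaving out a clone library. No list call of an alternative held with an estimated correlation.

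Within lines, the replicate block gave 9 calls in EXOSC3r cells and 3 for the difference of responses, and in PB cells it added HUERS-P1 (7 calls). Between lines it gave 22 calls under dox and 0 without dox. There it takes the spread between clones out of the error, so its calls are no evidence of a difference between conditions. Of its 4 list calls, 2 were those of dox in EXOSC3r cells and 2 were between lines without dox.

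No change that reversed had passed with the main settings. LTR7Y in PB cells (-0.05) became 0.0405 with total counts, by the shift of all sequences, and 0.0513 against the other 5 libraries. The ALR difference of responses became -0.000236 with total counts, -0.00164 with log2(TPM + 0.1), -0.0133 with effective length and -0.0070 with ACTB and GAPDH scaling, and -0.0921 to 0.16 leaving out a clone library. ACRO1 in EXOSC3r cells became -0.0075 with DESeq2 size factors, -0.0468 with total counts (shift -0.0408), -0.0097 with DESeq2, -0.00158 without a filter, -0.0029 with the block, -0.0034 without Alu, ACTB and GAPDH and -0.0019 with summed families, and -0.28 to 0.32 leaving out a clone library. HERVK there (0.08) became -0.0590 with total counts and -0.0495 with ACTB and GAPDH scaling. L1HS without dox became -0.0070 with DESeq2 size factors and -0.0070 with DESeq2. Leaving out a clone library gave, in EXOSC3r cells, MER22 -0.0528 to 0.0323, L1HS -0.0637 to 0.0229, HERVK -0.47 to 0.47, SVA_A -0.10 to 0.0077, LTR7C -0.40 to 0.0319 and the young L1 median -0.0792 to 0.0110, and without dox L1HS -0.0342 to 0.0533. The satellite median under dox became 0.0328 without a filter, 0.0658 with the filter on all 6 libraries and 0.0497 with log2(TPM + 1). Sequences near the floor, such as ACRO1 with 6.01 to 13.7 estimated counts outside PB cells with dox, limit what can be said of their changes.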

Other observations

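Some sequences below the threshold had changes of one sign in all 3 lines. Those given here had among the smallest p in their direction in both PB and EXOSC3r cells, so their shared sign follows in part from this choice. Sequences without any change also share a sign at times. How many of all tested sequences did so was not counted, so the shared sign is no support for a common response. HUERS-P1, an endogenous retrovirus, was higher with dox in PB cells (497 to 704 CPM) and in both clones (573 to 758 CPM and 548 to 682 CPM), with log2 changes of 0.50 ± 0.11 (edgeR, adjusted p = 0.32) and 0.36 ± 0.08 (adjusted p = 0.42). It passed in both conditions with the line as a block (adjusted p = 0.047 and 0.039). GOLEM was lower, by log2 changes of -0.46 ± 0.15 in PB and -0.42 ± 0.10 in EXOSC3r cells, and HERV4_I likewise by -0.39 ± 0.12 and -0.33 ± 0.09, none passing without the block. With it GOLEM passed in EXOSC3r cells (adjusted p = 0.041). In PB cells the sizes varied over the alternatives, though no sign changed. They lay between 0.20 and 0.59 for HUERS-P1, -0.68 and -0.37 for GOLEM, and -0.41 and -0.11 for HERV4_I. Over the 248 sequences with a mean of at least 100 CPM other than the ALR family, MER22, 6kbHsap and ACRO1, the dox responses had a Pearson correlation across sequences of 0.13 between PB and clone 1, 0.38 between PB and clone 2 and 0.16 between the clones (Spearman 0.15, 0.26 and 0.21). These are 3 of 9 such correlations computed; sequences are not independent replicates, and the lines share no library.

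HERVK went with dox from 6221 to 4101 CPM in PB cells, from 5050 to 7974 CPM in clone 1 and from 6437 to 4171 CPM in clone 2. LTR5_Hs, its promoter, went from 1423 to 1245 CPM, from 1343 to 1987 CPM and from 1553 to 1193 CPM. MER58A was estimated at 0.0099 counts in PB cells and at 150 in PB cells with dox, and at 328 and 16.02 in clone 1 and 154 and 384 in clone 2. It and LOR1b_LTR, the latter named after its values were seen, were the 2 sequences with under 1 estimated count in a library and at least 50 in another.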
